A study of Mus musculus with 6 samples.

How the data were processed

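RNA of whole Panc02 tumours was extracted with TRIzol, made into libraries with the VAHTS Universal V6 RNA-seq kit and sequenced as 150 bp paired-end reads on a NovaSeq platform, per the labels' protocols. The submitters' processing notes name HISAT2, HTSeq and R 3.2.0, without their roles. The genome build and annotation are not given in the sources used here, and no coordinates are printed. The authors deposited 1 table of 17352 genes with 1 column per library, an NCBI gene number and Gene Ontology terms. The deposited values are taken to be FPKM from the values themselves, because no header names their unit. In 75.6% of genes the 6 values were whole multiples of a step for each gene and library (tolerance 0.001), and 374 genes whose union exon length in GENCODE M21 gave a common total set the implied depth of 37500000 to 41100000 fragments. Column totals lay between 424661 and 466410 and varied by 3.46% (coefficient of variation), against 0.947% for totals weighted by exon length, which favours FPKM; a table of TPM restricted to some genes is not excluded.

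Samples were grouped by the genotype label into 3 deficient and 3 wild-type tumours. A count test had been chosen before the data were examined, with limma-trend on log2(value + 1) as the written fallback for FPKM, and the fallback was used. The fallback named no filter on low values. Genes with a mean FPKM under 0.5 were left out, a filter taken from a written alternative after the unit was known and before any test was run; it left 12257 genes, and with no filter only 10 higher and 8 lower genes were called, against 120 and 28. Linear models with a group term and no block were fitted with limma 3.58.1 in R 4.3.3, with a variance trend, pseudocount 1 and Benjamini-Hochberg adjustment; an adjusted p under 0.05 was a call. All p-values are two-sided except those of the hypergeometric tests.

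Of 33 gene lists fixed before the data were examined, 31 had at least 3 tested members and were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. Lists share genes, for example 6 of the 24 interferon gamma genes with other lists. The mitochondrially encoded list had 0 genes in the table and the sex-linked list 2 tested genes. Beyond the lists in the results, the camera adjusted p was 0.164 for neutrophil, 0.863 for endothelial, 0.102 for skeletal muscle, 0.931 for keratinocyte and skin, 0.0943 for tumour epithelial, 0.160 for epithelial-mesenchymal transition, 0.217 for erythroid, 0.560 for hypoxia and glycolysis and 0.863 for cholesterol synthesis genes. Some of these passed in other settings: tumour epithelial (0.0248) and erythroid genes (0.0479) without deficient 5, neutrophil genes (0.0357) without deficient 3, and hypoxia and glycolysis genes (4.29e-04) without wild type 5. Skeletal muscle genes passed with no filter (0.0119) and without deficient 4 (0.00326), wild type 2 (0.0473) or wild type 5 (0.00151), and epithelial-mesenchymal transition genes without deficient 4 (0.0177) or wild type 2 (4.52e-04). Gene Ontology terms of 10 to 500 genes (3167 terms) were tested against the 11816 annotated tested genes.

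Genes were named by a fixed rule: Anxa1; the 10 largest log2 fold changes in each direction among called genes with a mean log2 value of at least 1 and no overlap between groups, leaving out receptor and immunoglobulin segments and unnamed models; up to 4 members with the smallest p of each list described; and Cgas, Sting1, Ifnb1, Mertk, Cd8a, Gzmb, Adgre1 and Lyz2. The rule's minimum had been written for log2 CPM and was applied to log2(FPKM + 1). Kdm5d and Uty were named after their values were seen. 1 gene named by the rule is not reported here.

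The fit was tested on simulated data, with 200 changed genes among 12257 in 5 runs of the deficient against wild-type comparison. It recovered 52.4% of genes changed 1.5-fold, 83.6% of those changed 2-fold, 96.0% at 4-fold and 99.2% at 8-fold, with 5.05% false calls. Noise was drawn independently for each gene, and changes were planted only in genes above a minimum mean level. These rates may therefore not hold for correlated genes or for low genes. Alternatives were other scalings, pseudocounts, filters and thresholds, a replicate block and leaving out each library. Quantile normalization, a filter of FPKM of at least 1 in 3 libraries and an adipocyte covariate (mean log2 level of Adipoq, Plin1, Cidec, Lep, Cfd and Retn) were added after the data were seen.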

Results

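Whole-tumour RNA sequencing was performed on 6 tumours grown under the skin of mice from Panc02, a mouse pancreatic cancer cell line, and collected 4 weeks after implantation. In 3 of the tumours the host mice lacked annexin A1 (Anxa1) in myeloid cells, the lineage of macrophages, monocytes and granulocytes, and the other 3 hosts were wild type with a floxed Anxa1 gene. They are called deficient and wild type here, and tumours carry the numbers of their labels, 3, 4 and 5 for deficient and 2, 3 and 5 for wild type. The deposited table lists 17352 genes in FPKM, of which 15671 to 16035 had a value above 0 in a given library. The spacing of the low values implied totals of 37500000, 41100000 and 37700000 fragments for deficient 3, 4 and 5 and of 39500000, 38900000 and 38900000 for wild type 2, 3 and 5. Across genes, which are not independent replicates, log2 values correlated at 0.981 to 0.989 between libraries of the same group and at 0.965 to 0.984 between groups. The limma p-values of single genes measure the spread between these samples. The labels give a number to each tumour and do not say how the animals were paired. Hypergeometric p-values and those of camera at a preset correlation treat genes as independent or nearly so, and do not measure that spread. The label of every sample also carries the letters HFD, which the labels do not define, and a condition they may stand for is not analysed here.

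The comparison asked how expression in the tumour differed when myeloid cells lacked annexin A1, a phospholipid-binding protein. The study's title names efferocytosis (the uptake of dying cells), the cGAS/STING pathway of cytosolic DNA sensing and anti-tumour immunity. Anxa1 itself (NCBI gene 16952) was abundant in both groups. Its FPKM was 249.9, 330.2 and 290.5 in deficient 3, 4 and 5 and 341.8, 354.4 and 394.2 in wild type 2, 3 and 5. The group means were 290.2 ± 40.2 and 363.5 ± 27.3 (SD, n = 3), a log2 fold change of -0.33 (SE 0.12) that did not pass the threshold over all genes (limma adjusted p = 0.268). All 3 deficient libraries lay below all 3 wild-type libraries, and whole tumours also contain the Anxa1 RNA of cells in which the gene was not deleted.

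Immune genes were over-represented among the genes higher in the deficient tumours, where 120 of 12257 tested genes rose and 28 fell at an adjusted p under 0.05. Among the 118 higher genes with a deposited Gene Ontology term, 30 belonged to immune system process, where 3.97 would fall by chance (hypergeometric adjusted p = 4.53e-15), 11 to antigen processing and presentation and 7 to cytolysis. The largest increases among called genes that met the naming rule were in Gzmf, a granzyme, with a log2 fold change of 3.68 (SE 0.61, adjusted p = 0.043), Saa3, an acute-phase protein, at 3.28 (SE 0.54, adjusted p = 0.043), and Clec10a, a lectin of macrophages and dendritic cells, at 3.15 (SE 0.46, adjusted p = 0.034). Ly6d (2.71), Ly6c2 (2.56), Ubd (2.20), the B-cell-attracting chemokine Cxcl13 (2.20), Ms4a8a (2.08), Mzb1 (2.04) and complement factor B, Cfb (2.01), completed the 10 genes with the largest rise. Fold changes are on the scale of log2(FPKM + 1), which understates changes of low genes. List genes are counted as higher or lower on this scale. Groups did not overlap for 20.1% of tested genes, where 10% is expected by chance. The number of calls depended on single libraries and on the filter. Without deficient 3, 4 or 5 there were 17, 270 or 22 higher and 5, 66 or 9 lower genes. Without wild type 2, 3 or 5 there were 47, 7 or 34 higher and 18, 3 or 7 lower. With no filter on low values, 10 higher and 8 lower genes were called.

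**Figure D1:**
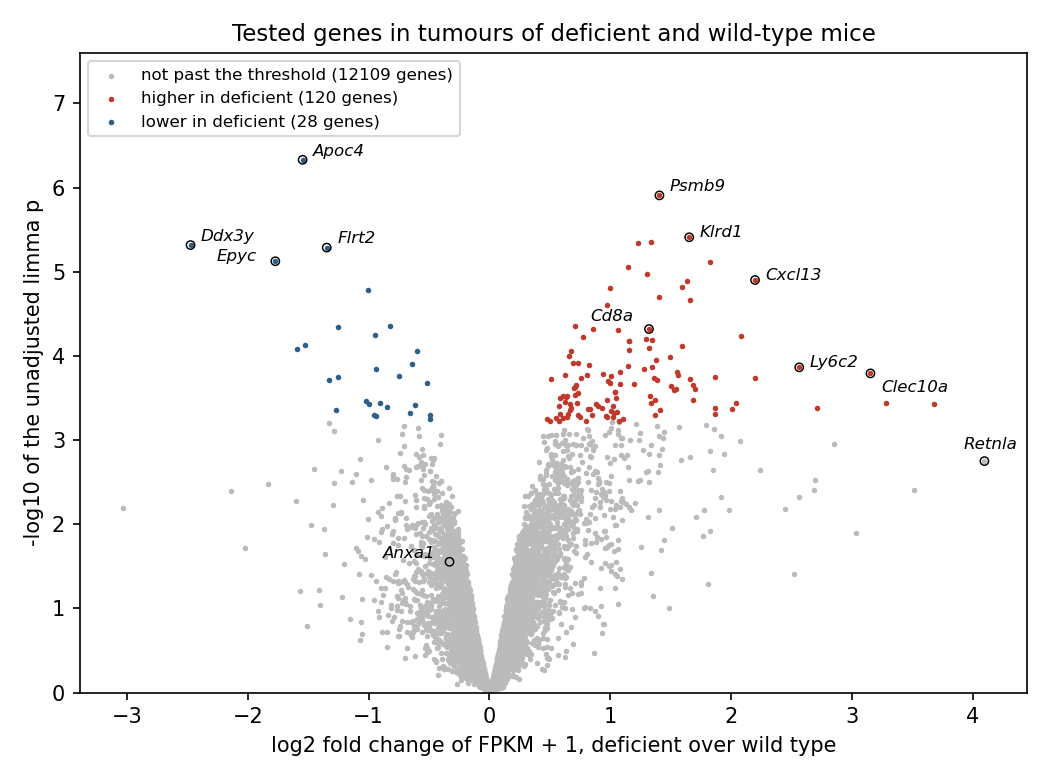
Each point is 1 of the 12257 tested genes, with the log2 fold change of FPKM + 1 (deficient over wild type, n = 3 each) on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis. The 120 genes called higher are red, the 28 called lower are blue, circled genes are named, and Anxa1 lies at -0.33 among the genes that were not called.

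The tumours of the groups also differed in Y-linked transcripts. Ddx3y, a Y-linked RNA helicase, had an FPKM of 0.0441, 0.126 and 0 in deficient 3, 4 and 5 and of 3.13, 5.26 and 6.79 in wild type 2, 3 and 5, with a log2 fold change of -2.47 (SE 0.22, adjusted p = 0.009). These values correspond to 8, 25 and 0 recovered fragments against 598, 992 and 1280. Eif2s3y fell as well (log2 fold change -0.997, adjusted p = 0.043). Kdm5d and Uty, too low to be tested, had mean FPKM of 0.0214 and 0.00894 in deficient against 0.961 and 0.839 in wild-type tumours. Y-linked genes therefore separated the same libraries as the genotype. Any difference described next lies between groups that also differed in these genes. Adipocyte markers moved with the groups too: 15 of 17 tested were higher in deficient tumours, with a median log2 fold change of 1.45 (camera adjusted p = 1.39e-05, adjusted p = 0.346 with an estimated correlation), although 0 passed over all genes and 10 did adjusted over the list alone. With the mean level of 6 adipocyte genes as a covariate, chosen after the data were seen, limma called 0 genes higher and 0 lower, and 147 of the 148 genes called without it had an unadjusted p under 0.05. Those 148 genes had been selected by their p in the same libraries, so that number is not independent support.

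Many genes of antigen presentation were higher in deficient tumours. All 19 genes of the MHC class I list were higher in deficient tumours on the log2 scale. Of these, 12 passed the threshold over all genes and 19 adjusted over the list alone. The immunoproteasome subunits Psmb9 and Psmb8 reached FPKM of 51.8 ± 1.77 and 163.6 ± 7.12 in deficient against 19.0 ± 2.56 and 64.5 ± 9.56 in wild-type tumours (SD, n = 3), log2 fold changes of 1.41 (SE 0.10, adjusted p = 0.008) and 1.34 (SE 0.12, adjusted p = 0.009). The peptide transporter Tap1 rose by 0.97 and the class I molecule H2-Q4 by 1.15 on the same scale. Of the 11 MHC class II genes, 11 were higher and 6 passed over all genes (9 adjusted over the list alone), including H2-DMb1 (1.40), H2-DMa (1.16), H2-DMb2 (1.15) and H2-Eb1 (1.08). The 23 tested genes of the interferon gamma response were all higher, with 6 past the threshold over all genes and 22 adjusted over the list alone. The guanylate-binding proteins Gbp4 and Gbp2 rose by 1.64 and 1.56, Serpina3g by 1.38 and the class I transactivator Nlrc5 by 0.61. Camera with a preset correlation gave adjusted p of 2.53e-23 for class I, 9.95e-12 for class II and 1.01e-20 for the interferon gamma list. The estimated correlation was 0.359, 0.454 and 0.616 in this order, against the preset 0.01. With an estimated correlation the camera adjusted p was 0.169 for each, whereas fry gave adjusted p of 0.0084, 0.0213 and 0.0335. H2 genes and guanylate-binding proteins belong to families of near-identical copies, so reads may be shared among their members.

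Cytotoxic lymphocyte transcripts were more abundant in the deficient tumours. Of 25 tested T cell and cytotoxic lymphocyte markers, 24 were higher, 7 past the threshold over all genes and 23 adjusted over the list alone (camera adjusted p = 7.91e-18, adjusted p = 0.169 with an estimated correlation). Cd8a and Cd8b1, the chains of the CD8 co-receptor, had FPKM of 6.88 ± 0.917 and 6.89 ± 1.43 in deficient against 2.18 ± 0.616 and 2.09 ± 0.456 in wild-type tumours (SD, n = 3), with log2 fold changes of 1.32 (SE 0.16, adjusted p = 0.024) and 1.35 (SE 0.17, adjusted p = 0.026). Perforin, Prf1, rose by 1.30 and the granzymes Gzma and Gzmb by 1.32 and 1.36. Of 5 tested NK cell markers, 4 were higher and 3 passed over all genes (4 adjusted over the list alone), namely the receptors Klrd1 (1.65) and Klrk1 (0.86) and Gzma, while Xcl1 stood at 1.15 (adjusted p = 0.109). Klra4 was lower, at -1.15 (limma adjusted p = 0.481), with a mean FPKM of 9.24 in deficient against 17.65 in wild-type tumours. The NK cell list holds 12 genes, most of them too low to be tested, and Gzma is also in the T cell list. The 5 tested B cell and plasma cell markers were all higher, with Mzb1 (2.04) and Cd79b (1.07) past the threshold over all genes and 4 adjusted over the list alone. Jchain was at 2.45 (adjusted p = 0.152). The camera adjusted p was 5.34e-05 for the NK cell list and 6.18e-05 for the B cell list, and the adjusted p was 0.169 and 0.274 with an estimated correlation.

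**Figure D2:**
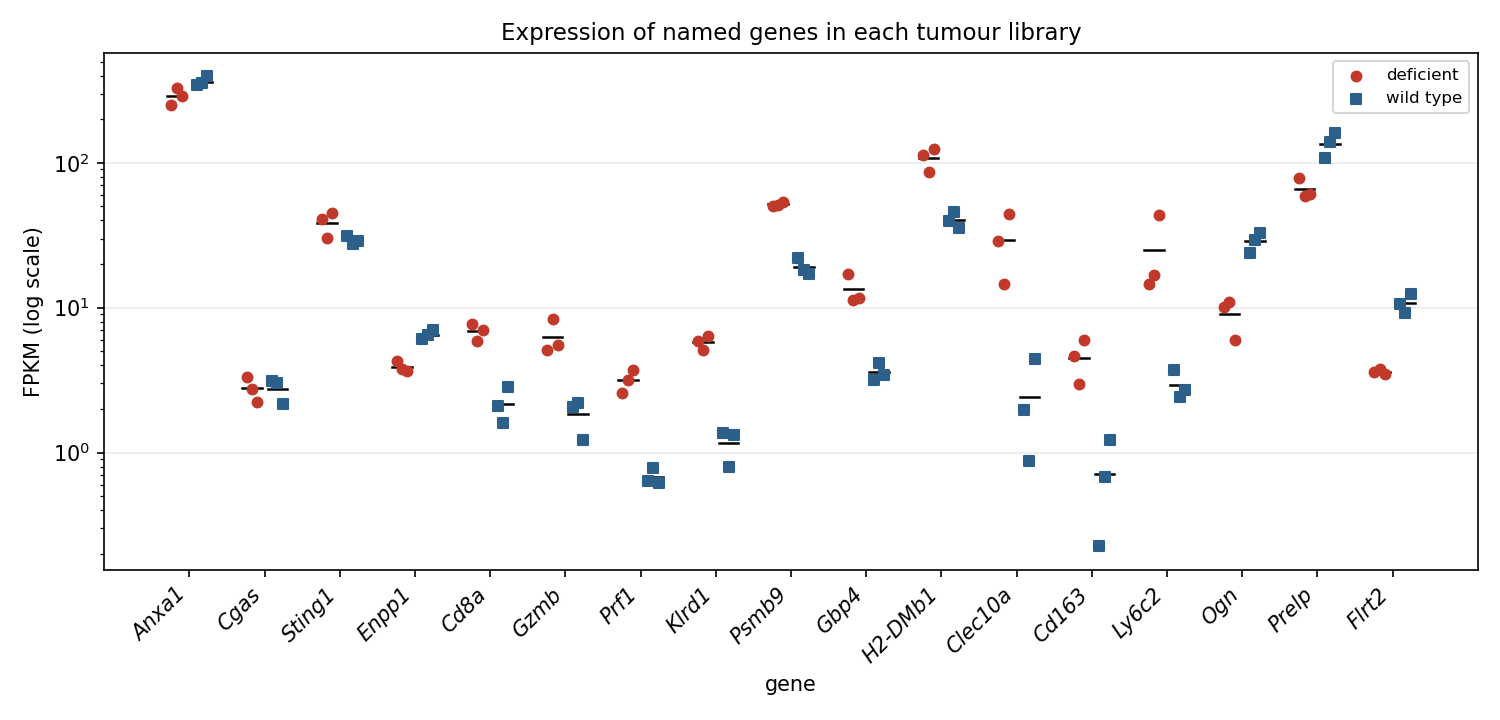
FPKM of 17 named genes, on a log axis, in each of the 3 deficient (red circles) and 3 wild-type (blue squares) tumour libraries, with black lines at the group means. Cd8a, Gzmb, Prf1, Klrd1, Psmb9, Gbp4, H2-DMb1, Clec10a, Cd163 and Ly6c2 lie higher in the deficient libraries, Enpp1, Ogn, Prelp and Flrt2 lie lower, and Cgas and Sting1 overlap between the groups.

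In the macrophage, M1-type and M2-type lists, Ly6c2, Ccr2, Clec10a and Cd163 rose past the threshold over all genes. Ly6c2, a surface marker of inflammatory monocytes, had FPKM of 24.87 ± 15.98 in deficient and 2.94 ± 0.687 in wild-type tumours (SD, n = 3; adjusted p = 0.034). Ccr2, the receptor for monocyte recruitment, rose by 1.39 (adjusted p = 0.034). These were the 2 of 18 tested macrophage and monocyte markers past the threshold over all genes, with 16 higher and 8 passing adjusted over the list alone. Adgre1 (F4/80) was at 0.20 (SE 0.16, adjusted p = 0.589) and Lyz2 at 0.48 (SE 0.28, adjusted p = 0.470), though Lyz2 was at 0.82 and passed (adjusted p = 0.030) without deficient 4. Among 15 genes of M2-type macrophages, 14 were higher, 2 passed over all genes and 9 adjusted over the list alone. Clec10a had FPKM of 29.3 ± 14.9 against 2.42 ± 1.82, the scavenger receptor Cd163 had 4.52 ± 1.51 against 0.706 ± 0.495 (log2 fold change 1.70, adjusted p = 0.038). Retnla was at 4.10 (SE 0.88, adjusted p = 0.086). None of the 14 M1-type genes passed over all genes and 4 did adjusted over the list alone, with 13 higher. Cxcl9 was at 1.43 (adjusted p = 0.063) and Tnf at 0.70 (adjusted p = 0.115). Of 26 inflammatory cytokines and chemokines 22 were higher, and Cxcl13 and Ccl8 (1.28) rose past the threshold over all genes, while 9 rose and 1 fell adjusted over the list alone. For immune checkpoint genes (14 of 15 higher) and dendritic cell markers (11 of 15 higher) 0 passed over all genes and 5 and 6 did adjusted over the list alone. Ido1 was at 0.98 (adjusted p = 0.080) and Cd274 (PD-L1) at 0.70 (adjusted p = 0.187). Camera adjusted p were 3.62e-07, 5.87e-07, 1.53e-04, 3.20e-05, 1.03e-04 and 0.00942 in this order of lists. The adjusted p was 0.274 for the first and 0.169 for each of the other 5 with an estimated correlation. The adipocyte covariate ended the calls of the macrophage (0.081), checkpoint (0.120) and dendritic cell (0.052) lists, and the filter of FPKM of at least 1 in 3 libraries that of the dendritic cell list (0.131).

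The lists closest to the study's subject differed in what they showed. All 36 tested genes of the type I interferon response were higher in deficient tumours on the log2 scale (median log2 fold change 0.47). In mean FPKM, Ifit3b (7.75 against 8.47) and Rsad2 (7.56 against 8.22) were lower in deficient than in wild-type tumours. In this list 0 genes passed over all genes and 3 did adjusted over the list alone. Zbp1, a nucleic acid sensor, was at 1.41 (SE 0.31, adjusted p = 0.090). Its camera adjusted p was 5.87e-07, but 0.525 with an estimated correlation. Wild type 2 lay above deficient 4 and deficient 5 in the mean of this list. In the cGAS/STING list 16 of 21 tested genes were higher, with a camera adjusted p of 0.257 and an adjusted p of 0.672 with an estimated correlation. Cgas was at 0.01 (SE 0.15, adjusted p = 0.991), with FPKM of 2.78 ± 0.538 and 2.76 ± 0.526 (SD, n = 3). Its sign turned under median-ratio, upper quartile and quantile scaling and without deficient 3 or wild type 5. Sting1 was at 0.37 (SE 0.14, adjusted p = 0.291), and at 0.54 (adjusted p = 0.044) without deficient 4. Ifnb1, below the filter, had mean FPKM of 0.113 and 0.310. Enpp1, which degrades cGAMP, fell by 0.62 (SE 0.10, adjusted p = 0.043), the 1 member past the threshold over all genes. This call was lost without any 1 of the 6 libraries (adjusted p from 0.056 without deficient 4 to 0.193 without wild type 3) and with no filter on low values (0.120). Such loss was common among the 148 calls, of which 10 remained without wild type 3 and 133 without deficient 4. Adjusted over the list alone, Samhd1 passed too (0.57). Of 33 tested efferocytosis genes 20 were higher, 0 passed over all genes and 3 passed adjusted over the list alone. Its camera adjusted p was 0.217, 0.046 without deficient 4, and the adjusted p was 0.672 with an estimated correlation. Nr1h3 was at 0.87, Cd36 at 1.94 and Mertk, a receptor for dying cells, at 0.31 (SE 0.20, adjusted p = 0.498). Of 12 annexins and formyl peptide receptors 9 were higher on the log2 scale. Among these is Anxa3 at 0.001, with a lower mean FPKM in deficient tumours (66.9 against 67.2). Of the 12 genes, 0 passed over all genes and 1 adjusted over the list alone, Fpr2 at 1.39 (adjusted p = 0.054). The camera adjusted p of this list was 0.146.

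**Figure D3:**
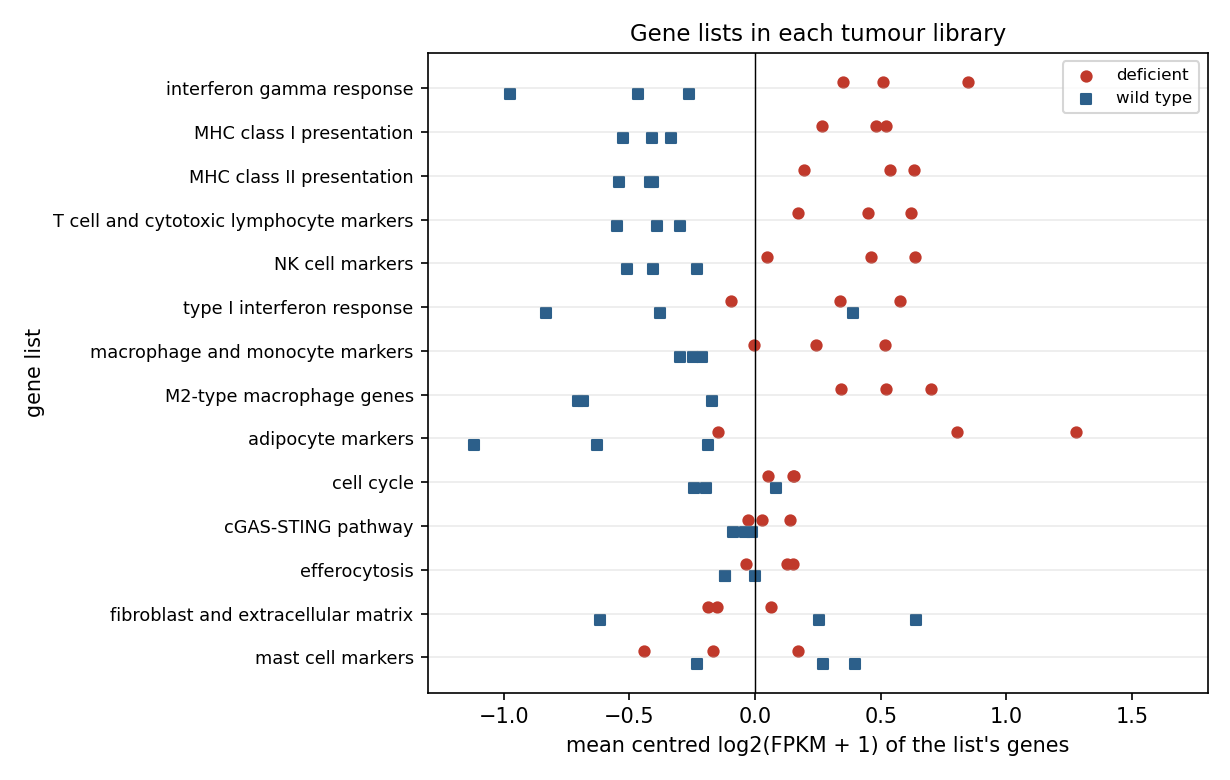
For 14 fixed gene lists, the mean of log2(FPKM + 1), centred for each gene on its mean over the 6 libraries, in each deficient (red circles) and wild-type (blue squares) library. The interferon gamma, MHC, T cell, NK cell, macrophage, M2-type and adipocyte lists do not overlap between groups. The type I interferon list overlaps, with wild type 2 at 0.39 above deficient 4 at 0.34 and deficient 5 at -0.10. The cell cycle, cGAS-STING, efferocytosis, fibroblast and mast cell lists overlap as well.

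Ddx3y had the largest decrease among the called genes that met the naming rule. Epyc, an extracellular proteoglycan, fell by 1.77 (SE 0.17, adjusted p = 0.010), with FPKM of 0.399 ± 0.254 against 3.75 ± 0.646 (SD, n = 3). Ogn, a small leucine-rich proteoglycan, fell by 1.59 (SE 0.21, adjusted p = 0.027), from 28.7 ± 4.48 in wild-type to 9.02 ± 2.66 FPKM in deficient tumours. Apoc4 (-1.55), Ecrg4 (-1.53), Flrt2 (-1.35), Coro6 (-1.26), Adgrf1 (-1.253), the matrix protein Prelp (-1.02) and the basement membrane collagen Col4a5 (-1.002) completed the 10 largest decreases. No Gene Ontology term passed among the 28 lower genes (lowest hypergeometric adjusted p = 0.763). In the list of fibroblast and extracellular matrix genes 16 of 23 were lower and 0 passed, over all genes or adjusted over the list alone. The groups overlapped in the centred log2 mean of this list. Wild type 2 (-0.62) lay below deficient 3 (-0.19), deficient 4 (0.06) and deficient 5 (-0.15). Lum was at -1.11 (SE 0.25, adjusted p = 0.0999) and Dcn at -0.65 (SE 0.22, adjusted p = 0.224). The 10 tested mast cell markers were all lower on the log2 scale, 0 past either threshold. In their centred log2 mean, wild type 2 (-0.23) lay below deficient 3 (-0.17) and deficient 4 (0.17). Camera adjusted p for the last 2 lists were 0.0155 and 0.00719, and the adjusted p was 0.660 and 0.525 with an estimated correlation. The fibroblast call was lost without deficient 3 (0.136) and wild type 3 or 5 (0.079 and 0.529), and with quantile normalization (0.071) or the adipocyte covariate (0.115). The mast cell call was lost without deficient 5 or wild type 5 (0.104 and 0.109). The adipocyte covariate ended it too and turned its direction (0.901).

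Proliferation genes and most respiration genes were slightly higher in the deficient tumours on the log2 scale. All 28 cell cycle genes were higher in deficient tumours on this scale, with a median log2 fold change of 0.23. The camera adjusted p was 1.58e-06, and 0.424 with an estimated correlation. Over all genes or adjusted over the list alone, 0 of them passed. In the centred log2 mean of the cell cycle list, wild type 2 (0.085) lay above deficient 3 (0.051). Of 28 oxidative phosphorylation genes 24 were higher, with a median of 0.12 (camera adjusted p = 0.0124, adjusted p = 0.660 with an estimated correlation), again 0 past either threshold. In their centred log2 mean, deficient 3 (-0.079) lay below wild type 2 (0.010) and wild type 3 (-0.065). Among 24 apoptosis and cell death genes 17 were higher, Casp1, an inflammatory caspase, rose by 0.66 (adjusted p = 0.031) and 6 passed adjusted over the list alone (camera adjusted p = 0.0491, adjusted p = 0.328 with an estimated correlation). The last 2 calls were lost without deficient 4 (0.340 and 0.176), deficient 5 (0.068 and 0.083) or wild type 5 (0.109 for both), and that of the apoptosis list without wild type 2 (0.204). Quantile normalization ended the oxidative phosphorylation call (0.098), and the filter of FPKM of at least 1 in 3 libraries that of the apoptosis list (0.052).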

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

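Quantile normalization, the filter of FPKM of at least 1 in 3 libraries and the adipocyte covariate were chosen after the data were seen. The 120 higher and 28 lower genes stayed within 1.5 times these counts under median-ratio and upper quartile scaling, pseudocount 0.1 and the filter of FPKM of at least 1 in 3 libraries. Higher genes numbered 10 with no filter on low values, 74 with quantile normalization, 0 with the adipocyte covariate, 425 at an unadjusted p under 0.05 and 1.5-fold, and 69 at an adjusted p under 0.05 and 2-fold. Lower genes numbered 8 with no filter, 0 with the covariate, 134 and 12. With leave-one-out, higher genes ranged from 7 (without wild type 3) to 270 (without deficient 4) and lower genes from 3 to 66. Of the 148 calls, those that remained called numbered 15, 133 and 27 without deficient 3, 4 and 5 and 45, 10 and 33 without wild type 2, 3 and 5. With no filter 12 of the 148 remained called. All 148 kept their sign in every setting that tested them, and the covariate, under which limma called 0 genes, left 147 of them at an unadjusted p under 0.05. Anxa1 stayed lower and uncalled in all 14 alternatives. Apart from the fewer libraries or degrees of freedom of leave-one-out and the covariate, the cause was not tested.

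The label numbers 3 and 5 occur in both groups, but samples with the same number did not deviate together (correlation of deviations across genes -0.09 for number 3 and -0.01 for number 5), and no label says that they pair mice. A fit with the number as a replicate block called 633 higher and 354 lower genes, Sting1 among them (log2 fold change 0.59, adjusted p = 0.023). With the block, the skeletal muscle (1.50e-05) and epithelial-mesenchymal transition (4.15e-05) lists passed, and the oxidative phosphorylation (0.251) and apoptosis (0.310) lists lost their calls.

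Among lists, the type I interferon call was lost with an estimated correlation (adjusted p = 0.525) and with fry (0.334), and the T cell call with an estimated correlation (0.169). All 19 list calls were lost with an estimated correlation and 9 of them with fry. The efferocytosis adjusted p ranged from 0.0463 (without deficient 4) to 0.604 with leave-one-out and was 0.488 in the opposite direction with the adipocyte covariate. That covariate also turned the direction of mast cell (adjusted p = 0.901), endothelial (0.00564), skeletal muscle (1.62e-14), adipocyte (0.345), keratinocyte and skin (0.144), epithelial-mesenchymal transition (0.901) and hypoxia and glycolysis (2.18e-07) lists, and of Sting1 (-0.0116), Mertk (-0.21), Adgre1 (-0.20) and Lyz2 (-0.31) on the log2 scale. The covariate also ended the calls of the macrophage (0.081), immune checkpoint (0.120), dendritic cell (0.052) and fibroblast (0.115) lists and brought the tumour epithelial list past the threshold (0.033). Keratinocyte genes turned with FPKM of at least 1 in 3 libraries (0.827) and the replicate block (0.922). With leave-one-out the adjusted p ranged from 0.0755 to 0.636 for endothelial genes (turned without deficient 5 and wild type 2) and from 0.00151 to 0.691 for skeletal muscle (turned without wild type 3). It ranged from 0.619 to 0.862 for keratinocyte genes (turned without deficient 3 and 5 and wild type 2 and 3) and from 4.52e-04 to 0.918 for epithelial-mesenchymal transition (turned without wild type 5). It ranged from 4.29e-04 to 0.879 for hypoxia and glycolysis (turned without deficient 5 and wild type 2 and 3) and from 0.177 to 0.918 for cholesterol synthesis (turned without deficient 3 and wild type 5). Cgas turned to -0.0111 with median-ratio scaling, -0.0163 with upper quartile scaling and -0.0263 with quantile normalization, and ranged from -0.115 to 0.111 with leave-one-out (turned without deficient 3 and wild type 5). The cause was not tested.

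The planned DESeq2, limma-voom and edgeR fits were not run, because the values are not counts and whole fragments were recovered for only 75.6% of genes. In simulated data 52.4% of 1.5-fold changes were recovered, so changes of that size are often missed.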

Other observations

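The tests of lymph node tissue, of library scaling, of host sex and of X-linked genes, and the adipocyte covariate as an added setting, were chosen after the results they bear on had been seen. Outside the groups already described, Lyve1, a marker of lymphatic endothelium and of some tissue macrophages, was the 1 of 15 tested endothelial markers past the threshold, over all genes and adjusted over the list alone (log2 fold change 1.68, adjusted p = 0.036). Clec4e, a lectin of neutrophils and macrophages, was the 1 of 15 tested neutrophil markers past the threshold over all genes (0.77, adjusted p = 0.026), with 4 adjusted over the list alone, and that list was called without deficient 3 (camera adjusted p = 0.0357) and not with all libraries (0.164). Both were picked out after their values were seen. The adipocyte markers with the smallest p were Retn, with FPKM of 4.92, 1.21 and 9.92 in deficient 3, 4 and 5 and 0.0787, 0 and 0.260 in wild type 2, 3 and 5 (log2 fold change 2.24, adjusted p = 0.095). Cidec (2.69, adjusted p = 0.122), Cfd (3.51, adjusted p = 0.122) and Thrsp (1.92, adjusted p = 0.133) followed.

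Lymphocyte, interferon gamma and antigen presentation genes were higher in the deficient tumours, with 32 called genes at a median log2 fold change of 1.12 (median SE 0.15). Library scaling is argued against, since the median of all tested genes was 0.0194, whereas lymph node tissue stays open: 12 B cell and lymph node stroma genes differed by a median of 0.0324 times the 4.49 FPKM by which 6 T cell genes differed (0.0245 to 0.0472 with leave-one-out) and 2 of them, Ccl21a (-0.138 FPKM) and Fcer2a (-0.0112), were lower, but 4 of the 12, Cd79b (3.44 FPKM), Cd79a (2.18), Fcrla (0.533) and Ms4a1 (0.532), exceeded 0.1 times it. With the adipocyte covariate the median was 0.856 (median SE 0.222), more than 0.5 times its former value. This cannot decide whether adipose tissue was the whole source. The covariate is a mean of 6 genes that correlates with the group (0.809, a descriptive value over 6 libraries). An imperfect measure of adipose tissue can leave a group difference behind even where that tissue is the cause. With the covariate 0 of the 32 genes remained called, and 32 had an unadjusted limma p under 0.05. The 32 genes were selected by their p in the same libraries, so the latter number is not independent support. The calls ended with a smaller median fold change, a wider median error and 3 in place of 4 residual degrees of freedom. Host sex cannot be told apart from genotype, since 0 libraries had the Y-linked level of the other group.

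Clec10a, Cd163 and Retnla were higher by a median of 3.15 (median SE 0.46). With the adipocyte covariate the median was 1.44 (median SE 0.365), too close to 0.5 times the former value to decide, and the 2 genes called without it, Clec10a and Cd163, were no longer called, with 3 in place of 4 residual degrees of freedom, while 2 of the 3 genes had an unadjusted p under 0.05. Macrophages of adipose tissue and a change of tumour macrophages therefore cannot be told apart, and both may contribute.

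Y-linked genes were nearly missing from the deficient libraries, and female hosts in that group and male hosts in the other could give this. The 4 X-linked genes known to escape inactivation had a median log2 fold change of 0.0383 (median SE 0.106). They cannot decide this, since tumour cells carry these transcripts too and the share from host cells is not known. The 4 Y-linked genes were at or below 0.126 FPKM in every deficient library. The macrophage marker Lyz2 was abundant there (mean FPKM 3241), so host cells were present. These values argue against male hosts in the deficient group. The Y-linked transcripts of wild-type tumours came mainly from host cells if the Panc02 cells of both groups were alike. Xist was not analysed here, and the labels used here give no sex.

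Other splits of the 6 libraries into 3 and 3 make 10 splits in all, too few for a share under 0.05. The real split called 120 higher and 28 lower genes and was the 1 split with as many, and the highest of the others called 0.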
